A study of Danio rerio with 52 samples.

How the data were processed

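Total RNA from whole zebrafish larvae was measured on 52 Agilent arrays, each labelled with the single dye Cy3, per the labels. The larvae were untreated or had been exposed to PolyIC or Pam3CSK4, and were collected 4, 8, 12, 24 or 36 h after exposure. This gave 15 groups of 3 or 4 arrays. Each array held 44787 spots, of which 1417 were control spots and 43370 were probes of 60 bases.

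The scanner intensity of each spot was extracted by the authors with Agilent Feature Extraction, version 10.5.1.1 per the file headers, while the submitters' processing notes name version 8.5. Per the file headers, the processed intensity was background-subtracted and spatially detrended, with a surrogate in place of values near or below the background, and it was not scaled between arrays. The raw mean and median spot intensity and the median of the local background stand beside it, per the file headers. The authors also deposited a table of log2 values for 29720 of the probes. Its scale is not stated in the sources used here. Compared with the scanner values, each of its columns kept the rank order of that array's median spot intensity, with Spearman's rho between 0.9986 and 1, and the column medians lay between 10.75 and 10.78. The values therefore match a log2 scale that was set nearly equal between arrays, while the method of that scaling and any centring of single probes remain unknown. The deposited table was used only as an alternative.

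The files do not pair probe identifiers with genes, give no genome positions, and no probe annotation was used here. Probes are therefore reported by identifier and by their sequence as listed in the files. The gene in the series title, the 23 gene lists and the cell type markers fixed before the data were examined could not be tested.

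For the main analysis, the log2 of the processed intensity minus the array's 75th percentile of it was used. Control spots were left out, as were 1266 spots with an outlier flag, and no spot was saturated. A probe was tested where it was well above background on at least 3 arrays, which kept 38639 probes. The 75th percentile of the processed intensity was between 1373 and 4615 per array, with a median of 3272, and between 78.0% and 86.3% of the probes were well above background. The mean Pearson correlation of an array with the others of its group was between 0.972 and 0.990. Among 200 pairs of tested probes with identical sequence, the median absolute difference in log2 change between PolyIC and control was 0.02. For arrays the number of arrays per group limits the precision.

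Linear models with 1 mean per group over all 52 arrays were fitted and moderated with limma 3.58.1 in R 4.3.3, with 37 residual and 3.07 prior degrees of freedom, and p-values were adjusted by Benjamini and Hochberg within each comparison. Probes with a missing spot were fitted exactly for their own arrays, where limma's F test uses an approximation. A probe was called at an adjusted p under 0.05. No label says that replicates were separate cultures or pools of larvae, so the p-values measure only the spread between these samples, which may be technical. All tests were two-sided.

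The rule for named genes, set before the data were examined, asked for the genes with a symbol and the largest changes among called genes, with the direction held in at least 4 of the 5 times for the means and without overlap between groups at single times. For tests of several times, it took the smallest p. Since no probe has a symbol, at most 2 probes that rose and 2 that fell per comparison are named by identifier, under otherwise the same rule. Probes that did not pass are named only for the Pam3CSK4 mean. These changes to the rule were made after the values were seen.

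A probe that was not well above background on any array of a group has only a bound there. Its fold is given as "at least", from the mean of the brighter group against the mean, per array, of the higher of the dim probe's own signal and the lowest signal among probes well above background. Bounds were also taken without each array of the brighter group in turn.

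Slides and scan days were read from the files. There were 15 slides and 3 scan days. Arrays were joined into 4 hybridization series, of 7, 15, 15 and 15 arrays, by shared slides, by shared agent and number in the sample descriptions, and by scan day. This definition was chosen after the data had been seen. Series 2 and 3 were scanned on the same day. Within a series the 3 agents lay largely on different slides, and no PolyIC array shared a slide with a control array. At no single time did arrays of different agents share a slide, so each time-matched comparison of agents is also one between slides. Series accounted for 46.9% of the variance within groups and scan day for 34.7%.

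The pairing check compared deviations from the group means. Control and Pam3CSK4 arrays of the same time and description number correlated above 0.1 in 16 of 16 pairs, with r between 0.18 and 0.67 across probes. For control and PolyIC arrays this held in 2 of 15 pairs with the description numbers and in 17 of 17 pairs with the series. The numbers in the titles did not pair the arrays. The description numbers of PolyIC differ from those of the other agents in the same series: series 1 holds number 1 of control and Pam3CSK4 with number 2 of PolyIC, and series 4 holds number 4 with number 1. Probes are not independent replicates, so these correlations describe the arrays.

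Longest runs of 1 base were counted in each probe sequence. The minimum of 5 bases for a run, of 6 bases for the sets chosen by sequence, the limit of 10 bases from the start of the sequence and the exact tests on them were chosen after the data had been seen. Fisher's exact test was used for shares of probes. The shift of a probe set was tested by permuting the group names within each time, with 100000 resamples. To follow the raised run probes in arrays that had no part in their choice, they were called without each series in turn and compared in that series between arrays of the same time. For the means over the 5 times, further splits of the arrays exchanged the agents only within a series and a time.

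The code was tested on simulated data with 37646 probes of which 200 were changed. For PolyIC against control over the 5 times, 93 of 100 probes changed by 1 and 100 of 100 changed by 2 (log2) were recovered. For Pam3CSK4 against control over the 5 times the counts were 88 and 100. For PolyIC against control at 4 h they were 53 and 90. The other single-time comparisons with control recovered 38 to 51 of the 100 probes changed by 1, and PolyIC at 12 h gave 10 false calls. The simulation shuffled the arrays over all groups, so it did not keep the series of the real data.

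Alternatives were other background corrections (normexp with an offset of 50), quantile or median scaling, other filters on dim probes, the authors' table, array weights, another variance model, only the groups compared, the slide, the scan day and the replicate number as blocks, and leaving out each replicate. Further alternatives chosen after seeing the data used the series as a block, left out probes with runs of C or G, left out series 1, or applied normexp without the local background. The 75th percentiles of the processed intensity in series 1 lay between 1373 and 2431.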

Results

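The study measured gene expression in whole zebrafish larvae exposed to one of a pair of immune agonists, and its title concerns the gene trim9 and the movement of macrophages. PolyIC is a synthetic double-stranded RNA of inosine and cytidine polymers that stands for viral RNA. Pam3CSK4 is a synthetic lipopeptide that stands for bacterial lipoproteins. Untreated larvae were collected at each time. The control and Pam3CSK4 groups held 4 arrays at 4 h, the control, PolyIC and Pam3CSK4 groups held 3 at 8 h, and the control group 3, the PolyIC group 3 and the Pam3CSK4 group 4 at 12 h. At 4 h PolyIC had 3 arrays. At 24 h and 36 h, control and PolyIC had 4 arrays each and Pam3CSK4 had 3. Between 78.0% and 86.3% of the probes were well above background per array. Values are log2 intensities relative to the array's 75th percentile, and differences are in log2 units with the standard error (SE) of the model unless an SD is named. The files do not pair probes with genes, so no gene, including trim9, could be followed by name.

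What PolyIC changed over the whole course was asked by averaging the 5 comparisons with time-matched controls. In PolyIC larvae, 52 probes were higher and 2 lower than in controls, of 38639 tested (limma, adjusted p under 0.05). The largest rises among the probes whose direction held across the times were in A_15_P101736 (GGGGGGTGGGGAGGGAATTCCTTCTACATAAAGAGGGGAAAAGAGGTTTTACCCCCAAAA), by 4.88 ± 0.68 (SE, adjusted p = 2.4e-05), and in A_15_P105003 (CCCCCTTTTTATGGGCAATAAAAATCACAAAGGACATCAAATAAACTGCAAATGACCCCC), by 4.18 ± 0.47 (SE, adjusted p = 5.5e-07). Both are dim in control larvae. At 4 h neither was well above background on any of the 4 control arrays, and PolyIC larvae had at least 104-fold more signal of the first and at least 13.1-fold more of the second. At 12 h the PolyIC arrays were spread, with −2.59, −7.94 and 0.30 for the first and −5.13, −8.63 and −4.41 for the second. The bounds there were 26.97-fold and 4.32-fold, and 7.46-fold and 2.44-fold without replicate 3. For A_15_P105003 the bound was 2.30-fold at 24 h and 2.68-fold at 36 h, and 1.26-fold and 1.76-fold without replicate 2, with 2 of 4 PolyIC arrays at 24 h and 1 of 4 at 36 h at or below the bound of the controls. The fitted differences rest on surrogate values in the dim groups. With normexp the rise of A_15_P105003 was 1.17 (adjusted p = 0.986). The lower probes were LOLS03144 (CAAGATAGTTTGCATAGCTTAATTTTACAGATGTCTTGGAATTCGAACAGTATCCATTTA), which fell by 1.50 ± 0.33 (SE, adjusted p = 0.0406), and LOL02357 (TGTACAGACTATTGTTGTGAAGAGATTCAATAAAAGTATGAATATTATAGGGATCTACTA), which fell by 0.32 ± 0.07 (SE, adjusted p = 0.0437). At 4 h LOLS03144 was well above background on all 4 control arrays and on 0 of 3 PolyIC arrays, so that controls had at least 6.67-fold more. The call of each fall was lost in 23 of 35 fits without 1 array, and with the slide as a random block (adjusted p = 1 and 0.946). In the authors' table LOLS03144 fell by 0.29 and LOL02357 by 0.15 (adjusted p = 1 and 0.969), and with normexp by 0.25 and 0.06 (adjusted p = 0.986 for each).

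The raised probes shared a feature of sequence. Of the 52 probes, 49 (94.2%) held a run of at least 5 C or 5 G, against 1083 (2.80%) of the 38639 tested (Fisher's exact test, p = 6.0e-73, chosen after the result was seen). Their median difference from controls was 2.14 at 4 h, 2.27 at 8 h, 1.52 at 12 h, 1.002 at 24 h and 0.93 at 36 h, and the group mean of each of the 49, which were called on the mean of these times, was higher at each time. The arrays differed: the mean of the 49 was 2.14, 3.12, −0.20 and 0.20 on the 4 PolyIC arrays at 24 h, relative to the control mean, and −0.33 on replicate 3 at 36 h. It lay above every control array of the same time on 14 of 17 PolyIC arrays, and on 2 of 4 at 24 h. In Pam3CSK4 larvae the median of the same 49 probes was 0.15, 0.16, −0.03, −0.23 and 0.00 at these times. Their mean lay above every control array of the same time on 5 of 17 Pam3CSK4 arrays, and it was 1.17 higher than in controls on Pam3CSK4 replicate 2 at 8 h. When all probes with such a run were left out, 3 probes were called over the 5 times, all raised.

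Sets of probes were then taken by their runs of 1 base. The criterion came from the raised probes, and the C set holds 23 of them and the G set 10, so these sets are not independent of the calls. The 119 probes with a run of at least 6 C were on average 0.50 higher in PolyIC than in control larvae, with a median of 0.15 (permutation p = 8e-05, adjusted 0.00064), with means of 0.67, 0.76, 0.41, 0.34 and 0.31 at 4, 8, 12, 24 and 36 h. The 86 probes with a run of at least 6 G were 0.30 higher on average, with a median of 0.00 (permutation p = 0.00041, adjusted 0.00164 for the mean). Without the raised probes the mean was 0.15 for the 96 others of the C set, 66 of them higher, and 0.02 for the 76 others of the G set. The 651 probes with a run of at least 6 A differed by −0.02 (adjusted permutation p = 0.614) and the 847 with such a run of T by −0.04 (adjusted permutation p = 0.0598). For Pam3CSK4 against control, the C set differed by −0.02 and the G set by −0.03 (adjusted permutation p = 0.678 for both). These p-values were adjusted over 8 tests. The permutations moved the group names within each time without keeping to series or slides, so these p-values do not decide about chance. With the hybridization series as a term, the differences in PolyIC larvae were 0.50 for the C set and 0.30 for the G set. Within the 4 series those of the C set were 0.46, 0.20, 0.56 and 0.71, and those of the G set were 0.02, 0.13, 0.48 and 0.38. On 13 of the 17 PolyIC arrays the mean of the C set lay above every control array of the same time, and on 2 of the 17 Pam3CSK4 arrays. The 4 other PolyIC arrays were replicate 2 at 12 h with −0.02, replicates 3 and 4 at 24 h with −0.12 and −0.02, and replicate 3 at 36 h with −0.20, relative to the control mean of their time. All but replicate 4 at 24 h are the 3 arrays of slide 8, in series 2.

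**Figure D1:**
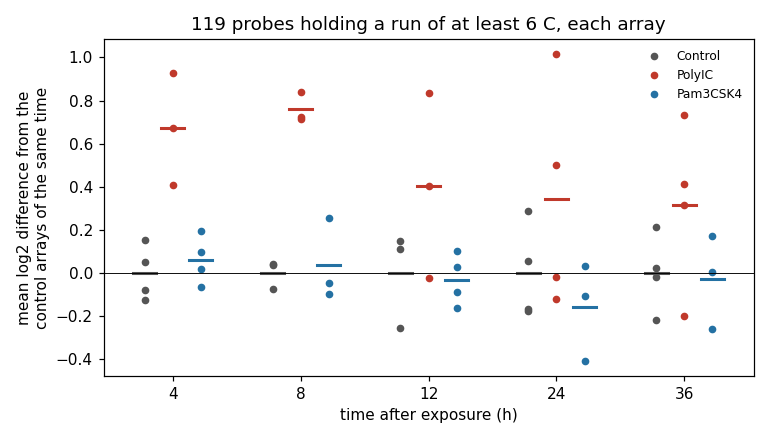
Mean log2 difference of the 119 probes with a run of at least 6 C from the mean of the control arrays of the same time, on the vertical axis, for each array (points) and group (bars show the group mean), by hours after exposure. All 3 PolyIC arrays at 4 h and at 8 h lie above the controls, while at 24 h the PolyIC arrays spread from −0.12 to 1.01.

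**Figure D2:**
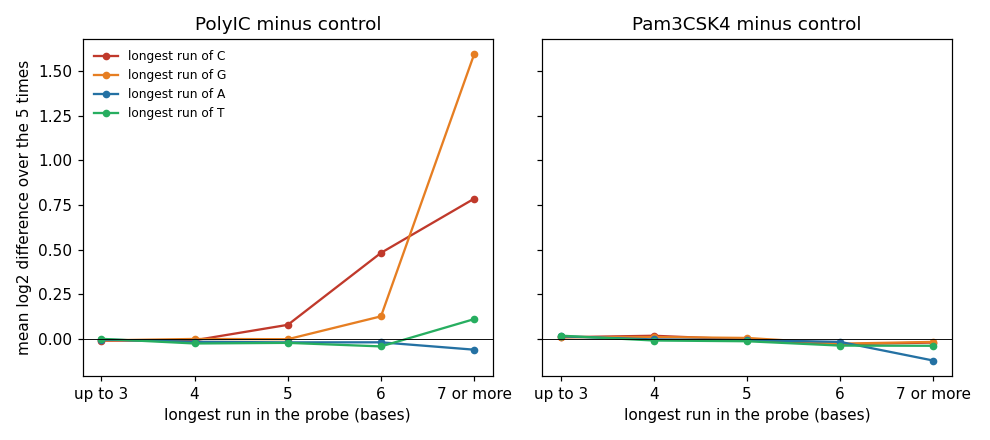
Mean log2 difference from control over the 5 times, on the vertical axis, of tested probes grouped by their longest run of each base in bases, for PolyIC (left) and Pam3CSK4 (right). In PolyIC larvae the mean is 0.08 at a longest C run of 5, 0.48 at 6 and 0.79 at 7 or more (median 0.14 at 6 and 0.26 at 7 or more), and 1.60 at a longest G run of 7 or more, the last from 10 probes. These means include raised probes that prompted the criterion: 21 of 112 at 6 C, 2 of 7 at 7 or more C and 5 of 10 at 7 or more G. Without raised probes the mean was 0.15 for runs of at least 6 C and 0.02 for at least 6 G.

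With the series as a block, 83 probes were called for PolyIC over the 5 times, 72 higher and 11 lower, and they included all 54. With the slide as a random block the count was 28, all among the 54, and 2 at 4 h. Within series 2, 574 probes were called, 156 higher and 418 lower, within series 4 57, all higher, and 0 in series 3 and in series 1, which left 1 residual degree of freedom. Within a series each agent had at most 1 array per time, so the times served as replicates, with 8 residual degrees of freedom in series 2, 3 and 4. Since no PolyIC array shared a slide with a control array, these counts cannot part the agent from the slide. The counts over all series are also between slides, which only the fit with the slide as a random block took into account. Within the scan day that held 30 arrays, 14 were called.

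At single times, the most probes were called at 4 h, where 10 were higher and 0 lower in PolyIC larvae than in controls. The largest rise among these 10 was in A_15_P120270 (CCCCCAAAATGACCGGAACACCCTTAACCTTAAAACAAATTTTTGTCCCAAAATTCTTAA), by 5.95 ± 1.04 (SE, adjusted p = 0.0306), or at least 17.7-fold. A_15_P105003 was 5.66 ± 1.05 higher (SE, adjusted p = 0.0306). Of the 10 probes, 9 held a run of at least 5 C or G (Fisher's exact test, p = 1.0e-13). With the series as a block, 31 probes were called. The count fell to 0 when any 1 of the 7 arrays was left out. At 8 h, 24 h and 36 h limma called 0 probes, with 1036, 343 and 580 at an unadjusted p under 0.05. With the series as a block it called 0 at each, with 3770, 873 and 2041 at an unadjusted p under 0.05. The PolyIC difference was not found to vary between times: limma called 0 probes, with 161 at an unadjusted p under 0.05. With the series as a block it called 0, with 994. In the main fit, all such unadjusted counts for the agonists lie below 5% of the tested probes, the share that chance alone gives. The main fit, which leaves the series in the spread, was thus conservative, and a count of 0 called probes is weak evidence of no change.

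At 12 h a single probe, LOL04721 (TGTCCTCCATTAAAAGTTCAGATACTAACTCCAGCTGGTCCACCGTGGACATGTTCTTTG), was lower than in controls under both agonists. It fell by 2.57 ± 0.43 in PolyIC larvae (SE, adjusted p = 0.0235) and by 2.53 ± 0.41 in Pam3CSK4 larvae (SE, adjusted p = 0.00864). Its level was −5.40 ± 0.98 in controls (SD, n = 3), −7.97 ± 0.83 in PolyIC larvae (SD, n = 3) and −7.93 ± 0.51 in Pam3CSK4 larvae (SD, n = 4) at 12 h, and −7.95 ± 0.42 in controls at 8 h (SD, n = 3). Both comparisons share the same 3 control arrays, so they are not independent. Without control replicate 3 the adjusted p was 0.629 for PolyIC and 0.644 for Pam3CSK4, and without control replicate 2 it was 0.246 and 0.193. Leaving out PolyIC replicate 1 or 2 gave 0.82 and 0.259, and leaving out Pam3CSK4 replicate 2 gave 0.148. With normexp the differences were −1.03 for PolyIC and −0.10 for Pam3CSK4 (adjusted p = 0.989 for the latter), and neither was called. Both calls were also lost when only the compared groups were fitted. The PolyIC call was lost with quantile normalization (adjusted p = 0.148) and with the slide as a random block (adjusted p = 0.127).

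What Pam3CSK4 changed was asked in the same way. At 8 h, 2 probes were higher than in controls and 0 lower. A_15_P108789 (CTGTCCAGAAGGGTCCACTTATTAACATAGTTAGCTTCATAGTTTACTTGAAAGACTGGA) rose by 5.66 ± 0.70 and A_15_P100602 (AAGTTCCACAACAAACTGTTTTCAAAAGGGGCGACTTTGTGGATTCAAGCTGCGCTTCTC) by 3.2 ± 0.40 (SE, adjusted p = 1.9e-05 for each). Both were well above background on 3 of 3 Pam3CSK4 arrays and on 0 of 3 control arrays at 8 h, which bounds the rises at 10.1-fold and 1.83-fold or more. The spot of A_15_P100602 in Pam3CSK4 replicate 3 had an outlier flag, so its level and bound rest on 2 Pam3CSK4 arrays. A_15_P108789 was at −5.80, −6.34 and −2.47 on the Pam3CSK4 arrays, and without replicate 3, which had the lowest share of probes well above background (78.0%), the rise was 4.46 and the bound 4.40-fold. Both calls were lost when only the compared groups were fitted (adjusted p = 1 for each) and with normexp, where the rises were 1.97 and 0.70 (adjusted p = 1 for each), so they depend on the variance from other groups and on the background correction. Neither was well above background on any Pam3CSK4 array at 4, 12, 24 or 36 h. A_15_P108789 was, however, well above background on 1 of 3 PolyIC arrays at 12 h, where replicate 2 was at −6.46. The Pam3CSK4 difference varied between times for these 2 probes (adjusted p = 0.0031 for A_15_P108789 and 0.0012 for A_15_P100602) and for no other probe at this threshold, with 163 at an unadjusted p under 0.05. Without Pam3CSK4 replicate 1, 8 probes were called at 8 h, and without replicate 2, 4 were.

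At 4 h, 24 h and 36 h limma called 0 probes for Pam3CSK4, with 873, 237 and 338 at an unadjusted p under 0.05. With the series as a block the counts were 1, 0 and 0. With array weights 1391 were called at 4 h, where Pam3CSK4 replicates 3 and 4 had weights of 7.87 and 7.26, and 11 at 24 h. Over the 5 times limma called 0 probes, with 1619 at an unadjusted p under 0.05. With the series as a block it called 18, 3 higher and 15 lower, with 4051 at an unadjusted p under 0.05. With array weights it called 670. The probe with the smallest p, A_15_P107376 (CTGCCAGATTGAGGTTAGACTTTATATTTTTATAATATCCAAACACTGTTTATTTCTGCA), differed by −0.63 ± 0.13 (SE, adjusted p = 0.274) and did not pass; with the series as a block the difference was −0.62 ± 0.10 (SE, adjusted p = 0.00598). Its mean was below that of controls at each of the 5 times. Within series 2, 362 probes were called, 170 higher and 192 lower, within series 3 635, 204 higher and 431 lower, 0 in series 1 and in series 4, and 7 within the scan day that held 30 arrays. As for PolyIC, the counts within a series rest on at most 1 array per agent and time and cannot part the agent from the slide.

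The agonists were then compared with each other. Over the 5 times, 57 probes were higher in PolyIC than in Pam3CSK4 larvae and 0 were lower. A_15_P101736 was higher by 4.45 ± 0.69 (SE, adjusted p = 1.7e-04) and A_15_P120270 by 4.05 ± 0.47 (SE, adjusted p = 1.1e-06). Both calls were lost with normexp, where the differences were 2.17 and 1.06 (adjusted p = 0.414 and 1). These fitted differences rest on surrogate values where Pam3CSK4 larvae had no array well above background: there the bounds were at least 28.4-fold for the first at 12 h, and at least 7.35-, 3.56- and 3.08-fold for the second at 12, 24 and 36 h. Without the PolyIC array that lowers them most these fell to 7.86-fold for the first and to 3.95-, 1.93- and 2.06-fold for the second. At 24 h A_15_P120270 was at −4.43, −3.76, −9.30 and −8.16 on the PolyIC arrays, against −9.86 on average in Pam3CSK4 larvae. Of the 57 probes, 54 (94.7%) held a run of at least 5 C or G (Fisher's exact test, p = 1.1e-80), and without such probes 2 were called. At 8 h, A_15_P108789 and A_15_P100602 were lower in PolyIC than in Pam3CSK4 larvae, by −5.31 ± 0.70 (SE, adjusted p = 1.1e-04) and −2.73 ± 0.40 (SE, adjusted p = 7.2e-04), with bounds of at least 10.49-fold and 1.90-fold. With normexp the differences of these 2 probes were −1.70 and −0.44, and neither was called, nor was either when only the compared groups were fitted. Without Pam3CSK4 replicate 3 the difference of A_15_P108789 was −4.11 and its bound 4.57-fold. Without Pam3CSK4 replicate 2 the call of A_15_P100602 was lost (−2.16, adjusted p = 0.138). At 4, 12, 24 and 36 h limma called 0 probes, with 655, 330, 245 and 458 at an unadjusted p under 0.05. With the series as a block 7 probes were called at 4 h and 73 over the 5 times. Within the scan day that held 30 arrays, 0 were called over the 5 times.

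The course of expression in untreated larvae was followed over the 5 times. Among controls 5546 of 38639 probes differed between the 5 times (limma F test). Relative to 4 h, 3012 of them were higher and 2534 lower at 36 h, and 1817 and 350 by at least 2-fold. The control arrays of 36 h lay on other slides than those of the earlier times, so changes to 36 h cannot be parted from the slide. At 24 h, 3108 were higher and 2438 lower than at 4 h. A_15_P103108 (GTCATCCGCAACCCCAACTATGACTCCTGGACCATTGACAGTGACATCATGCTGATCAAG) rose from −4.09 ± 0.51 at 4 h to 2.85 ± 0.10 at 36 h (SD, n = 4, adjusted p = 2.4e-13), a difference of 6.94. A_15_P120229 (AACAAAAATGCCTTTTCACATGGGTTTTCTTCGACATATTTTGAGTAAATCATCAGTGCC) rose from −3.03 ± 0.06 to −0.36 ± 0.20 (SD, n = 4, adjusted p = 6.2e-13).

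The probes with the smallest p did not move in one direction. A_15_P110290 (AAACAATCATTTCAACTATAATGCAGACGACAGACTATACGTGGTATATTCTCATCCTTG) was at −4.94 ± 0.67 at 4 h, −0.28 ± 0.21 at 24 h and −6.37 ± 0.72 at 36 h (SD, n = 4, adjusted p = 7.6e-17), and was not well above background on any control array at 8 h or 12 h. LOLS01767 (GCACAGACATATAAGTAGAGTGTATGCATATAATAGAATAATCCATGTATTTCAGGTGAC) was at −6.86 ± 0.65 at 4 h and −2.46 ± 0.44 at 24 h (SD, n = 4, adjusted p = 1.2e-16), and was not well above background on any control array at 8, 12 or 36 h.

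**Figure D3:**
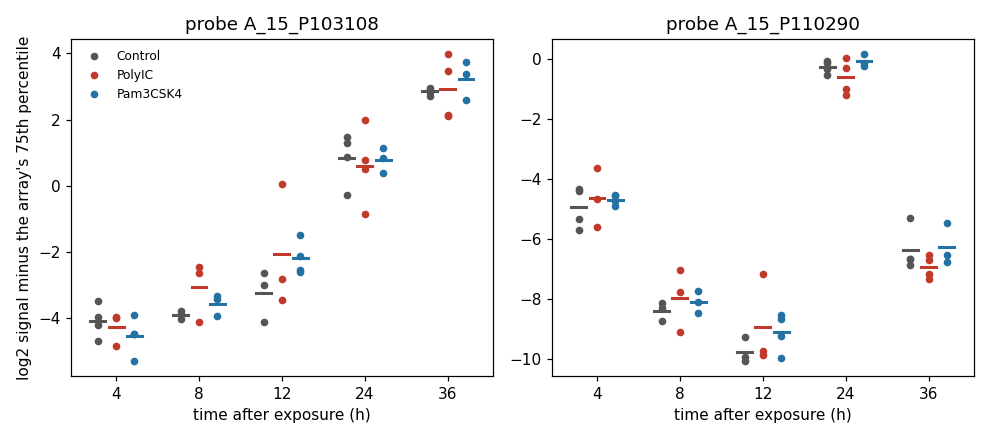
Log2 intensity relative to the array's 75th percentile, on the vertical axes, of the probes A_15_P103108 (left) and A_15_P110290 (right) on each array (points) with group means (bars), by hours after exposure and agent. The control means of the left probe go from −4.09 at 4 h to 2.85 at 36 h, and those of the right probe reach −0.28 at 24 h.

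The changes from 4 h were also compared with those in treated larvae, which are other arrays. Across all 38639 tested probes, the change from 4 h in controls was correlated with that in Pam3CSK4 and in PolyIC larvae. The values of r were 0.373 and 0.111 at 8 h, 0.628 and 0.563 at 12 h, 0.819 and 0.850 at 24 h, and 0.886 and 0.896 at 36 h. These changes were taken without a series term. Series 1 had control and Pam3CSK4 arrays at 4 h but none at 8 h, and no PolyIC array at either time. The r values at 8 h can therefore reflect the series as well as the time. Of the 5546 probes that differed between times in controls, 66.6% and 64.6% had the same sign at 8 h. This was so for 85.0% and 86.7% at 12 h, 96.4% and 98.2% at 24 h, and 98.8% of them in both at 36 h. At 8 h there was little change to share: the median absolute change of these probes in controls was 0.19, as for all probes, against 0.25, 0.67 and 0.84 at 12, 24 and 36 h. Probes are not independent replicates, and the 5546 probes were chosen by their change in controls. With the series as a block 10795 probes differed between times among controls, and within the scan day that held 30 arrays 2596 did. On the 4 slides that held control arrays of both 4 h and 24 h, 5545 probes differed between these times with the slide as a term, 3137 higher and 2408 lower at 24 h.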

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

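The tests of the gaps below and of differences between times follow rules fixed before the data were examined, while the counts over other splits of the arrays and the test of the scan day were chosen after the result was seen.

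The Pam3CSK4 difference from control varied between times for 2 probes, A_15_P108789 and A_15_P100602. Of 100 splits of the arrays into groups of the same sizes, 11 gave at least 2 probes, so chance is not excluded. The highest other split gave 488, which points to a structure of the samples. These splits ignore the series, and none within series were made for this result. With the series as a block limma still called both probes (adjusted p = 0.00391 for A_15_P108789 and 2.3e-04 for A_15_P100602).

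In groups of 4 arrays, sets of values were examined for an array far from the other 3, and 10 of them (9.52%) had a gap beyond Dixon's limit, where chance gives about 5%. The value given is the gap as a share of the range. The 75th percentile of the signal had such a gap in the control groups at 4 h (0.897) and 24 h (0.836), in both cases at the array of series 1, with 1675 and 1373. Series 1 also held the array apart for A_15_P120229 in Pam3CSK4 larvae at 4 h (0.941), for A_15_P120270 in controls at 24 h (0.887) and for LOL02357 in PolyIC larvae at 36 h (0.863). Arrays of series 4 stood apart for A_15_P120229 in PolyIC larvae at 24 h (0.956) and for A_15_P110290 in controls at 36 h (0.864). Series 3 held the array apart for A_15_P107376 in controls at 24 h (0.831) and for LOLS01767 in controls at 36 h (0.863), and series 2 for LOLS03144 in PolyIC larvae at 36 h (0.965).

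Deviations from the group means followed the hybridization series, which accounted for 46.9% of the variance within groups. The tables argue against the scan day as the whole cause, since arrays of series 2 and 3 were scanned on the same day and correlated at −0.10 on average in 210 pairs, against 0.34 within these series. They also argue against the scaling of the arrays, since the share was 47.3% after quantile normalization and 51.7% in the authors' table. What the series mark, such as separate batches of larvae, stays open, and no biological explanation was tested.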

How the results depend on the processing

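The tests with the series as a block, without probes holding runs, without series 1 and with normexp without local background were chosen after the result was seen; all others were planned.

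Median scaling, no filter on dim probes, the filter on groups and the trend and robust variance model moved none of the 21 counts by over 1.5 times. Median scaling shifted the median of all probes by up to 0.18 between arrays. The cause of a move was not tested. LOL04721, A_15_P108789 and A_15_P100602, the only probes called for PolyIC or Pam3CSK4 at 12 h and for Pam3CSK4 at 8 h against either group and between times, are not in the authors' table, so they could not be called in it and its counts of 0 there say nothing about them.

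For PolyIC at 4 h (10 in the main setting) the count was 0 with normexp, 18 with only the groups compared, 0 with array weights, 23 with scan day, 2 with slide as a random block (consensus correlation 0.447), 0 with the title numbers as replicate block, 18 with the description numbers, 31 with series, 0 with normexp without local background, and 0 without run probes, also with series. For PolyIC at 8 h (0) it was 41 with weights and 1 with description numbers within each time. For PolyIC at 12 h (1) it was 0 with either normexp, quantile normalization, the authors' table, only the groups compared and slide, and 26 with weights; at 36 h (0) it was 36 with weights. For PolyIC over the 5 times (54) it was 8 with normexp, 28 with slide, 82 with description numbers, 83 with series, 82 with series within each time, 3 without run probes, and 6 with series and without run probes. The 28 were all among the 54, as were the 8.

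For Pam3CSK4 at 4 h (0) the count was 1391 with weights, and 1 with series, with or without run probes. At 8 h (2) it was 0 with either normexp, the authors' table and only the groups compared, and 4 with weights. At 12 h (1) it was 0 with the same 4 settings and 42 with weights; at 24 h (0) it was 11 with weights. Over the 5 times (0) it was 670 with weights, 2 with description numbers within each time, 18 with series, 42 with series within each time, 16 with series and without run probes, and 1 without series 1. The Pam3CSK4 difference between times (2) gave 0 with either normexp and the authors' table, 7 with weights, and 1 with description numbers or series within each time and without series 1.

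For PolyIC against Pam3CSK4 at 4 h (0) the count was 5 with only the groups compared, 12 with weights, 7 with scan day and 7 with series. At 8 h (2) it was 0 with either normexp, the authors' table and only the groups compared, and 62 with weights. With weights it was 2 at 24 h and 80 at 36 h. Over the 5 times (57) it was 5 with normexp, 159 with weights, 37 with normexp without local background, 2 without run probes, and 6 with series and without them. Time among controls (5546) gave 2894 with normexp, 3302 with only the groups compared, 8374 with scan day, 1359 with description numbers within each time, 10795 with series and 10609 with series and without run probes. Array weights ranged from 0.214 to 7.87.

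The pairing by replicate block moved no other count by over 1.5 times. The one reversed value was LOLS01767 at 36 h against 4 h, 0.18 with normexp. Normexp put the 25th percentile above 8 (log2) on 9 arrays, and the same 9 had spots whose local background exceeded the spot by over 1000. Without local background the PolyIC count over the 5 times was 36, all among the 54, while the counts for PolyIC at 4 h and 12 h, Pam3CSK4 at 8 h and 12 h and PolyIC against Pam3CSK4 at 8 h were 0 either way. At 4 h A_15_P120270 rose by 2.01 with normexp and by 1.84 without local background.

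Leaving out 1 replicate gave 0 to 0 probes for PolyIC at 4 h, 0 to 1 at 8 h (1 without PolyIC replicate 1), 0 to 2 at 12 h (2 without control replicate 2) and 46 to 62 over the 5 times. It gave 2 to 8 for Pam3CSK4 at 8 h, 0 to 2 at 12 h, 0 to 1 at 36 h (1 without control replicate 4) and 0 to 1 over the 5 times (1 without control replicate 1 at 12 h). It gave 2 to 6 for PolyIC against Pam3CSK4 at 8 h (6 without Pam3CSK4 replicate 1, 5 without replicate 2), 46 to 63 over the 5 times, 0 to 1 for the PolyIC difference between times (1 without PolyIC replicate 1 at 8 h or control replicate 2 at 12 h), 1 to 3 for that of Pam3CSK4 (1 without control replicate 2, Pam3CSK4 replicate 2 or replicate 3 at 8 h) and 4482 to 5825 for time among controls.

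Not run were the mean of probes per gene symbol and the alternatives for gene lists and for single genes, for want of gene names, and the slide as a fixed term could not be fitted. Levels near the background are surrogate values, so signal over background limits the folds of dim probes.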

Other observations

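The tests on runs of bases, on GC content and on the series, and the counts over other splits of the arrays, were chosen after the result was seen, while those on the slide, the scaling, the overlapping probes and the 24 h peak had their tests set before their values were seen.

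Some probes peaked or dipped at 24 h. Apart from A_15_P110290 and LOLS01767, whose levels prompted the question, 121 probes were higher in controls at 24 h than at the mean of 12 h and 36 h, 74 of them by at least 2-fold, and 65 were lower (limma, adjusted p under 0.05). In the treated larvae the median of the same contrast was 1.26 for the first set and −0.65 for the second, and all 121 and all 65 had the same sign as in controls.

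A daily rhythm is a candidate explanation of the 24 h peak, as 12 h and 36 h lie 1 day apart. If so, the first set of probes would also stand higher at 4 h than at 12 h, while a single peak at 24 h would leave no difference. The arrays of 4 h and 12 h shared slides in Pam3CSK4 larvae but lay on different slides in PolyIC larvae. In the treated larvae, whose arrays did not enter the choice of probes, the median difference between 4 h and 12 h was 0.36 for the 121 probes, with quartiles of 0.04 and 1.07, and 97 (80.2%) were higher at 4 h. For the 65 probes it was −0.12, with 26 higher, and for the 38451 other probes 0.01. This is consistent with a rhythm for part of the probes; the labels give no clock time or lighting, so a change with age that rises and falls stays open.

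The differences between 4 h and 24 h among controls are not explained by the slide alone, since 5545 probes differed on the same slides with the slide as a term. This check cannot reach 36 h, since the control arrays of 36 h lay on other slides. Of 100 splits of the control arrays, 2 gave at least the 5546 probes of the real one, the real one included. The highest other split gave 6440, which points to a structure of the samples. These splits ignore the series, and no splits within series were made for this count, so they do not decide about chance.

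The probes raised in PolyIC larvae carry runs of C or G, and PolyIC itself is a polymer of inosine and cytidine, which pair with C and G. A candidate explanation is that the polymer was carried in the extracted RNA and bound to such probes. Since only labelled material gives signal, the polymer would have to be labelled itself or bind together with labelled RNA, which was not tested. Probes with a C run of at least 6 were 0.50 higher in PolyIC larvae and not in Pam3CSK4 larvae (−0.02), but 23 of these 119 are raised probes that prompted the choice, and the 96 others were 0.15 higher, so the polymer stays open. The tables argue against overall GC content as the whole cause. Of 4194 probes without a run with a GC content of at least 53.3%, 2 were raised, against 49 of the 1083 with a run. A smaller part of GC content stays open, since these 2 are among the 3 raised probes without a run. The median difference of the 4194 was 0.048, but a median cannot decide this, as that of the G set was 0.00. The tables also argue against the series, since run probes called without a series were higher by 1.08 or more in that series. Transcription of the genes behind these probes stays open, because 0 tested probes without a run shared at least 20 bases with a raised run probe.

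Among 583 probes with a run of at least 5 C, the raised ones more often had the run near the start of the listed sequence. With the run starting within the first 10 bases 24 of 112 were raised, against 20 of 471 others (Fisher's exact test, p = 4.6e-08). The limit was chosen after the raised probes were seen, so this p-value describes those probes and is no independent test. Run probes called without series 1, 2, 3 or 4 differed in the series left out by 1.81, 1.08, 2.78 and 3.05 in PolyIC larvae and by 0.36, 0.00, 0.30 and 0.01 in Pam3CSK4 larvae. At the time with the lowest value the PolyIC mean was −0.36 in series 2.

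Other splits of the same arrays were set beside each count. For PolyIC against control over the 5 times 2 of 100 splits gave at least the real 54 probes, the real one included. The highest other split gave 3387, which points to a structure of the samples, and the count with the series as a block was 83. These splits do not keep to the series, so they do not decide about chance. Where the agents were exchanged only within a series and a time, 1 of 100 splits gave the real 54, with 0 as the highest other. With the series as a block 1 of 100 gave the 83, with 29 as the highest other. Only the real split within series reached these counts, but exchanging single arrays mixes the slides. PolyIC and control arrays shared no slide, so a chance difference between slides is not excluded. For PolyIC against Pam3CSK4 over the 5 times 1 of 100 splits gave the real 57, with 3 as the highest other (0 among splits within series). Arrays of these agents at the same time also lay on different slides, so the same limit holds. For PolyIC at 4 h 1 of 35 gave the real 10, with 6 as the highest other; these splits ignore the series, and the 7 others that part as many series pairs, with 0 at most, are too few for a share under 0.05. For Pam3CSK4 at 12 h 2 of 35 splits gave at least the real 1, and the highest other gave 24, so chance is not excluded; that split parts the arrays of scan day 2 from the rest. With scan day as a block the count was 1.

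A real count of 0 is reached by every split, so these splits say nothing about chance. This was so in 35 of 35 splits for PolyIC at 24 h, where the highest other split gave 4525 and parted series 1 and 2 from series 3 and 4, which points to a structure of the samples; the count with the series as a block was 0. It was also so in 35 of 35 for PolyIC at 36 h (highest other 1), for Pam3CSK4 at 4 h (3), 24 h (1) and 36 h (8), and for PolyIC against Pam3CSK4 at 4 h (449), 12 h (2), 24 h (1) and 36 h (0). In 100 of 100 splits it was so for Pam3CSK4 over the 5 times (highest other 6136, and 0 within series) and for the PolyIC difference between times (41). With the series as a block Pam3CSK4 gave 18 probes over the 5 times, reached by 1 of 100 splits within series, with 1 as the highest other.

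With 3 against 3 arrays there are 10 splits, too few for a share under 0.05. The real count and the highest other were 0 and 1 for PolyIC at 8 h (10 splits gave as many), 1 and 0 for PolyIC at 12 h (1 split), 2 and 1 for Pam3CSK4 at 8 h (1 split), and 2 and 1 for PolyIC against Pam3CSK4 at 8 h (1 split). At single times, splits that part as many series pairs as the real one gave at most 1 probe, for Pam3CSK4 at 36 h and for PolyIC against Pam3CSK4 at 8 h.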
